A study of Homo sapiens with 4 samples.

How the data were processed

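RNA sequencing was done on total RNA of Huh7 cells, a human hepatoma line, from a control clone (clone 1) and from a clone lacking TTP and BRF1 (clone 18, called DKO), with 2 libraries of each. Per the labels' protocols, 1 µg of total RNA received ERCC spike-in RNA before ribosomal RNA was depleted, libraries were made with a kit that keeps the strand, and reads of 80 bases were taken from 1 end. The authors deposited 1 table of whole-number read counts per gene and library, with no normalization. The submitters' processing notes name the genome build hg38, STAR 2.5.3a, featureCounts of Subread 1.6.3 and DESeq2. The gene annotation, the strand setting of the counting and the rule for reads with several matches are not given in the sources used here. Near-identical genes can therefore share or lose reads, and reads of overlapping antisense genes may not have been kept apart, so values of such genes are uncertain.

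The deposited count table held 42261 features, of which 92 were ERCC spike-ins and 42169 were genes. The spike-ins were left out of library sizes and of the main test. Gene symbols were matched to GENCODE release 29, an annotation of the same genome build, and 40751 gene rows (96.64%) matched exactly 1 gene. A further 54 rows matched several genes and 1364 matched none, and these kept their counts but had no position, type, GC content or length. Positions in the text are from that annotation on hg38, counted from 1. The 3′ UTRs were built from its coding and exon records, and the longest of each gene was searched for UAUUUAU.

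Counts assigned to genes were 9685798 and 12507263 in the control libraries and 10271428 and 16430228 in the DKO libraries. A count of 3 corresponded to 0.310, 0.240, 0.292 and 0.183 CPM (counts scaled to the library total) in the same order. Levels near these values rest on few reads. The reads carried no molecular identifiers, so counting precision is an upper limit on the true precision. Libraries of the same clone were compared before averaging, and the chi-square per degree of freedom over genes was 36.1 for the control libraries and 29.8 for the DKO libraries, so neither clone held the same library in duplicate. The labels do not say whether libraries of a clone came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Each genotype is represented by 1 clone, and clone and genotype are therefore the same contrast.

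DKO was compared with control in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, library sizes were scaled by TMM factors, and the quasi-likelihood test was fitted to all 4 libraries with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are described as higher or lower, and 13359 genes were tested. Levels are mean CPM ± SD over the 2 libraries of a clone, and log2 fold changes are DKO over control with their standard errors (SE). A comparison of 2 libraries with 2 cannot reach a 2-sided exact permutation p under 0.333 for a single gene, and the gene tests rest on the spread that edgeR shares between genes. In 5 simulated data sets with the means and library sizes of this comparison, 13359 genes and 200 changed genes, the test called 65.8% of genes changed by 1 log2 unit and 94.6% of those changed by 2 log2 units, and 7.2% of its calls were unchanged genes. A further 30 genes were raised by 0.58 log2 units. Simulated genes were independent, with no GC trend and no effect shared by same-numbered libraries. The 7.2% therefore need not hold for the data.

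Before the data were examined, 28 gene lists with 775 members in all, the rule for named genes and most alternatives were fixed. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation, with ranks and with fry. With an estimated correlation, camera uses the residual degrees of freedom of the libraries, which are few with 4 libraries. That form therefore has little power here, whatever the correlation of a list. On simulated data of the same comparison, camera called 5 of 5 lists of 30 raised genes and 0 of 100 unchanged lists. Genes were drawn independently there, so the simulation does not test camera on lists whose members vary together. In the data, the estimated correlation was 0.56 for TGF-beta and YAP targets, 0.60 for histone genes and 0.99 for mitochondrial mRNAs. The named genes are ZFP36, ZFP36L1, ZFP36L2, BRF1 and PPP1R15A; the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among those past the threshold with a mean of at least 10 CPM and both DKO libraries on the same side of both control libraries; up to 3 members, by adjusted p, of each list past its threshold or with at least 4 members past the gene threshold; the leading member of each other list; and the genes that a hypothesis of the closing section concerns. A few further list members past the threshold are named in the text, and these were chosen after their values were seen.

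Alternatives were DESeq2 size factors, total counts and ERCC totals in place of TMM; no filter and a filter of 1 CPM and 20 counts; the replicate number as a block; leaving out each library; DESeq2 1.42.0 and limma-voom in place of edgeR; a test against a 1.5-fold change; and a fit with trends over GC content and gene length removed. Fold changes were also smoothed along each chromosome as the median of 50 neighbouring tested genes, and a segment was a run of at least 20 genes whose smoothed value passed 0.304 in size, the 95th percentile of the largest value in 100 shuffles of gene order. In simulated data with 13117 genes and a block of 100 genes shifted by 0.5 log2 units, 85% of the block was found. The segments were defined after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The value of 1 gene past the threshold is not reported here. Half-lives were not computed, since 1 time after actinomycin D was analysed here.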

Results

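Transcript levels were measured in Huh7 cells, a line derived from a human liver tumour, in a control clone and in a clone in which the genes for TTP and BRF1 had been knocked out (DKO). TTP is the product of ZFP36. BRF1 is here butyrate response factor 1, the product of ZFP36L1. Both proteins bind AU-rich elements in 3′ UTRs and recruit enzymes that remove the poly(A) tail. All cells received DMSO for 3 h and then actinomycin D, which blocks transcription, at 5 µg/ml for 10 min before harvest. The control clone and the DKO clone each gave 2 libraries. Counts on genes totalled 9685798 and 12507263 in the control libraries and 10271428 and 16430228 in the DKO libraries, and between 18644 and 19436 genes had at least 1 count per library.

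The mRNAs of the targeted genes were not lower in the DKO libraries. ZFP36 (chromosome 19, 39406813 to 39409412, hg38) had 26.6 ± 3.89 CPM in the control libraries and 37.0 ± 0.235 CPM in the DKO libraries (SD, n = 2), a log2 fold change of 0.48 (SE 0.21, edgeR adjusted p = 0.207). ZFP36L1 (chromosome 14, 68787660 to 68796253) had 122 ± 14.8 CPM and 133 ± 18.1 CPM, a log2 fold change of 0.13 (SE 0.20, edgeR adjusted p = 0.775). The related gene ZFP36L2 (chromosome 2, 43222402 to 43226609), whose product binds the same elements, differed by 0.22 (SE 0.19, edgeR adjusted p = 0.564). The gene with the symbol BRF1 (chromosome 14, 105209286 to 105315589), which encodes an RNA polymerase III factor and shares only the name, differed by -0.46 (SE 0.24, edgeR adjusted p = 0.311), and passed without control replicate 1 at -0.70 (edgeR adjusted p = 0.0315). The kind of mutation in the knockout is not given in the sources used here, and a mutation that stops the protein need not lower the mRNA. The mRNA levels therefore do not check the genotype labels.

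**Figure D1:**
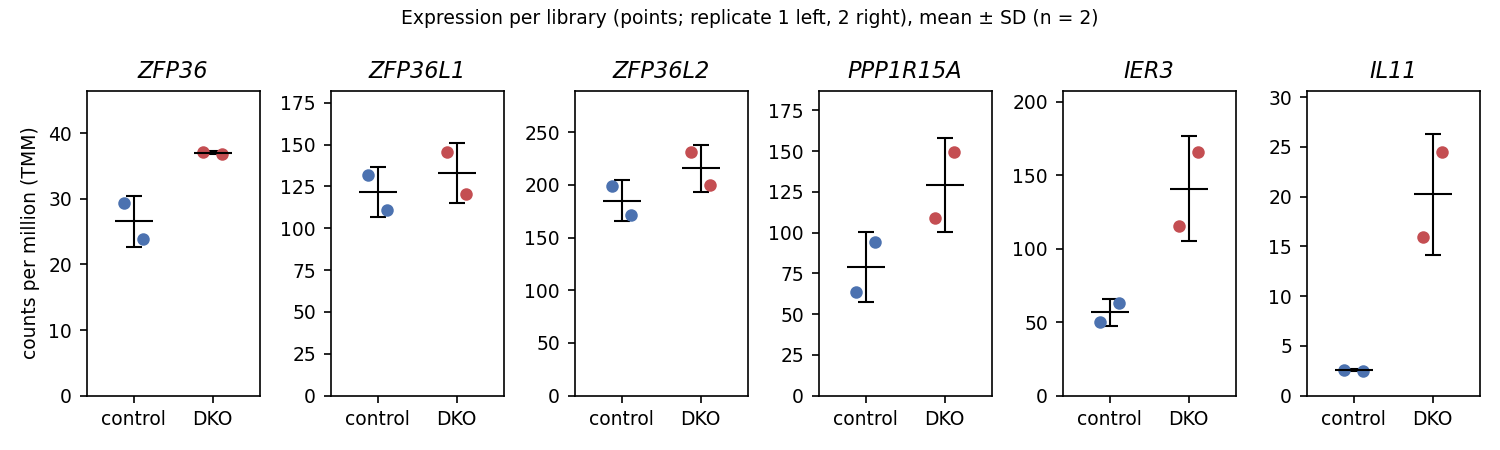
Normalised expression (CPM, vertical axis) in each library for the ZFP36 family, PPP1R15A, IER3 and IL11; points are libraries, horizontal lines are means and bars are SD over the 2 libraries of a clone. ZFP36 had 26.6 CPM in control and 37.0 CPM in DKO on average, and IL11 had 2.57 and 20.2 CPM.

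PPP1R15A encodes GADD34, the stress-induced subunit that directs a phosphatase to the translation factor eIF2α, and turnover of its mRNA is the subject that the series names. PPP1R15A mRNA (chromosome 19, 48872392 to 48876057) had 78.9 ± 21.5 CPM in the control libraries and 129 ± 28.9 CPM in the DKO libraries (SD, n = 2). The mean was 1.64-fold higher in DKO, and both DKO libraries lay above both control libraries. The log2 fold change of 0.71 (SE 0.23) did not pass the threshold (edgeR adjusted p = 0.0851). It passed without control replicate 2 at 1.02 (edgeR adjusted p = 0.00214), and was 0.46 without control replicate 1 and 0.46 without DKO replicate 2. It also passed when no filter was used (0.73, edgeR adjusted p = 0.0197) and when trends over GC content and length were removed (0.75, edgeR adjusted p = 0.00396). Its 50 chromosomal neighbours had a median of -0.05.

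Across the transcriptome, the genes named by a fixed rule rose or fell as follows. UNC13D, which primes secretory granules for release, rose from 0.456 ± 0.0678 to 38.0 ± 4.92 CPM (log2 fold change 6.36). AKR1C1, a reductase of steroids and carbonyls, rose from 4.99 ± 1.63 to 72.8 ± 8.37 CPM (3.88), with the reservation that AKR1C2 is nearly identical in sequence. CDH17, the liver-intestine cadherin, fell from 87.4 ± 1.27 to 4.18 ± 0.919 CPM (-4.40). RELN, which encodes the secreted protein reelin, fell from 434 ± 37.5 to 85.3 ± 0.00346 CPM (-2.35).

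The others among these that rose were the neural adhesion molecule L1CAM (3.16), the cytokine IL11 (2.98), the calprotectin subunit S100A9 (2.89), SPP1, which encodes osteopontin (2.76), and the matrix proteoglycan BGN (2.66). They were followed by the inhibin subunit INHBE (2.12), the interferon-induced membrane protein IFITM3 (2.08), whose reads can overlap those of IFITM2, and the adhesion molecule PECAM1 (2.03). Those that fell were the mucin-like PARM1 (-3.12), the collagen COL14A1 (-2.98), the hedgehog ligand IHH (-2.58) and the receptor PDGFRA (-2.07). These were followed by the telomerase subunit TERT (-2.04), NDRG1 (-1.93), the sphingolipid enzyme subunit SPTLC3 (-1.89) and USH1C, a scaffold of the brush border (-1.86). UNC13D lies on chromosome 17 (75827225 to 75844717), AKR1C1 on chromosome 10 (4963253 to 4983283), CDH17 on chromosome 8 (94127171 to 94217303) and RELN on chromosome 7 (103471784 to 103989516). The largest adjusted p among these 20 genes was that of SPTLC3 (edgeR adjusted p = 0.000866). INHBE, COL14A1, TERT and NDRG1 lie in chromosomal segments in which neighbouring genes moved in the same direction, with neighbour medians of 0.34, -0.37, -0.60 and -0.68. All 20 genes kept their call in each of the 4 fits without 1 library, and with ERCC totals all but INHBE, IFITM3 and PECAM1 did.

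**Figure D2:**
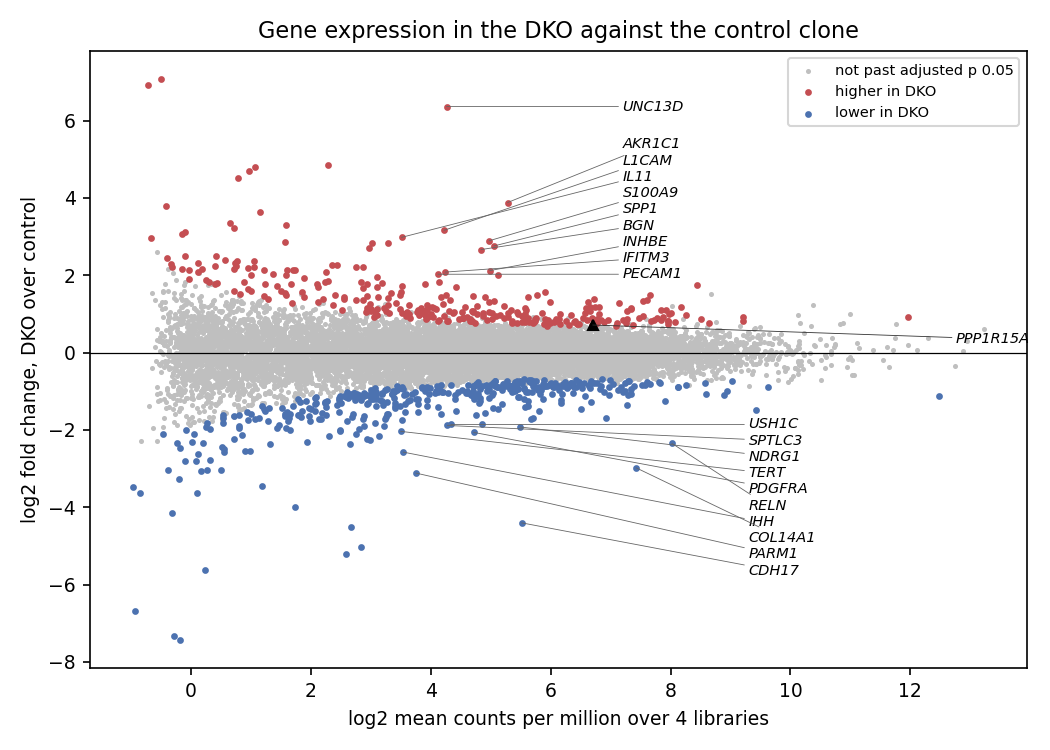
Log2 fold change of DKO over control (vertical axis) against log2 mean CPM over the 4 libraries (horizontal axis) for the 13359 tested genes; coloured points passed an edgeR adjusted p of 0.05. The 20 named genes and PPP1R15A (triangle, 0.71) are labelled, from UNC13D at 6.36 to CDH17 at -4.40.

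Of 13359 genes tested, 718 passed (299 higher and 419 lower in DKO), and 458 of them differed at least 2-fold (197 higher and 261 lower). Protein-coding genes made up 681 of the 718 (279 higher and 402 lower). The libraries of the clones did not overlap for 49.8% of tested genes, where chance gives 33.3%. With ERCC totals as library sizes, 329 genes passed (22 higher and 307 lower), and the median gene shifted by -0.68, so directions in the text are relative to the median gene. The count depended on which library was left out. Leaving out 1 library also leaves the replicate numbers unbalanced between the clones, and deviations of same-numbered libraries correlated at 0.470. Such fits therefore also carry any effect that same-numbered libraries share. In all 4 fits without 1 library, 127 of the 718 genes passed in the same direction (64 higher and 63 lower).

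Among known targets of the ZFP36 family, a list fixed from general knowledge, 5 of 49 tested members rose, 2 fell and 42 did not pass. IL11 rose 7.89-fold. IER3, an early response gene, rose from 56.7 ± 9.17 to 141 ± 35.6 CPM (log2 fold change 1.31, edgeR adjusted p = 0.00332). The chemokine CCL20 (0.97), the transcription factor KLF2 (1.14) and the cytokine signalling inhibitor SOCS3 (1.13) also rose. The transcription factor CEBPD (-1.59) and the kinase PLK2 (-0.85) fell, and PLK2 lies in a segment of chromosome 5 with a neighbour median of -0.42. Adjusted over the list alone, 8 rose and 3 fell. The list's median was 0.14 and it did not pass (camera adjusted p = 0.0693). With the replicate number as a block it passed (0.13, camera adjusted p = 0.0280), though the labels state no pairing. It passed without control replicate 2 (median 0.28, camera adjusted p = 0.000105), without DKO replicate 1 (0.30, camera adjusted p = 0.000104), without a filter (0.15, camera adjusted p = 0.0166), with GC and length trends removed (0.18, camera adjusted p = 0.04999) and with genes outside the segments alone (0.14, camera adjusted p = 0.0370). Its median was 0.09 without control replicate 1 (camera adjusted p = 0.626) and 0.04 without DKO replicate 2 (camera adjusted p = 0.646), and with an estimated correlation its adjusted p = 0.981. SOCS3 was not called by DESeq2 (1.12, DESeq2 adjusted p = 0.0677). Without control replicate 2, 9 members rose and 2 fell, without control replicate 1, 5 and 3, without DKO replicate 1, 6 and 0, and without DKO replicate 2, 1 and 1. Without DKO replicate 2, IER3 (1.03, edgeR adjusted p = 0.0781), CCL20 (0.89), KLF2 (0.92), SOCS3 (0.70) and PLK2 (-0.84) did not pass. Without DKO replicate 1, CEBPD (-1.37, edgeR adjusted p = 0.0592), CCL20 (1.05) and PLK2 (-0.85) did not.

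No target of ATF4, the transcription factor of the integrated stress response, passed. Of 33 ATF4 targets 26 had positive values, with a median of 0.23 (camera adjusted p = 0.0693), and the leading member was the cationic amino acid transporter SLC7A1 (0.70, edgeR adjusted p = 0.0512), which passed without control replicate 1 (0.64) and without control replicate 2 (0.75). At an unadjusted edgeR p under 0.05, 6 members were higher and 1 lower. DESeq2 called 1 and limma-voom 0. The ATF4 list passed with the replicate number as a block (0.24, camera adjusted p = 0.0280). Without control replicate 1, 1 ATF4 target rose and 1 fell, and without control replicate 2, 6 rose. The list passed without control replicate 2 (0.36, camera adjusted p = 1.36e-05), without DKO replicate 1 (0.33, camera adjusted p = 0.000297), without a filter (0.23, camera adjusted p = 0.0345), with ranks (camera adjusted p = 0.0236) and with GC and length trends removed (0.29, camera adjusted p = 0.0233). Its median was 0.11 without control replicate 1 (camera adjusted p = 0.837) and 0.09 without DKO replicate 2 (camera adjusted p = 0.694), and with an estimated correlation its adjusted p = 0.981. Of 19 eIF2 kinases, phosphatases and eIF2B subunits 17 had positive values and none passed (median 0.16, camera adjusted p = 0.165); 2 were higher at an unadjusted edgeR p under 0.05, DESeq2 and limma-voom called 0, and 1 rose without control replicate 1 and 1 without control replicate 2. Among 27 chaperones and unfolded protein response genes SEC61B, a subunit of the ER translocon, rose (0.88, edgeR adjusted p = 0.0491), and 0 passed when adjusted over the list alone (median 0.17, camera adjusted p = 0.0889). That list's median ran from 0.14 to 0.17 in the fits without 1 library. With all 4 libraries kept, the list passed without a filter (0.18, camera adjusted p = 0.0321), with ranks (camera adjusted p = 0.0464) and with the replicate number as a block (0.18, camera adjusted p = 0.0496). With an estimated correlation its adjusted p = 0.981. Of its members 4 rose and 1 fell without control replicate 1. SEC61B did not pass without control replicate 2 (0.52), without DKO replicate 1 (1.04) or without DKO replicate 2 (0.70). Of 18 heat shock genes none passed (median -0.04, camera adjusted p = 0.945), with HSP90AA1 leading at -0.72 (edgeR adjusted p = 0.0747) and passing without control replicate 1 (-0.76, edgeR adjusted p = 0.0473). At an unadjusted edgeR p under 0.05, 3 heat shock genes were higher and 1 lower, DESeq2 and limma-voom each called 1, and without control replicate 1, 3 rose and 2 fell.

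Target genes of TGF-beta and YAP signalling were higher as a list at the preset correlation (camera adjusted p = 0.00321; adjusted p = 0.981 with an estimated correlation), with 4 of 18 members risen, 0 fallen and 14 not passed. The muscle ankyrin-repeat gene ANKRD1 rose from 107 ± 19.6 to 298 ± 86.7 CPM (1.48, edgeR adjusted p = 0.00178). The ligand TGFB1 rose from 101 ± 10.8 to 225 ± 24.7 CPM (1.16, edgeR adjusted p = 0.00341), and the matrix protein CTGF by 0.81 (edgeR adjusted p = 0.0419). Adjusted over the list alone, 5 rose. The median was 0.35. The list did not pass without control replicate 1 (0.18, camera adjusted p = 0.355) or without DKO replicate 2 (0.24, camera adjusted p = 0.115), and in the latter 1 of 18 members rose and TGFB1 (edgeR adjusted p = 0.0638) did not pass either. CTGF did not pass without control replicate 1 (0.63), DKO replicate 1 (0.88) or DKO replicate 2 (0.73).

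Replication-dependent histone genes were also higher as a list at the preset correlation (camera adjusted p = 0.00350; adjusted p = 0.981 with an estimated correlation), with 3 of 19 risen, 0 fallen and 16 not passed. HIST1H2BH (0.98), HIST1H2BC (0.93) and HIST1H2BJ (0.78) encode copies of histone H2B and resemble each other in sequence. Adjusted over the list alone, 5 rose. The median was 0.40, and 0.20 with GC and length trends removed (camera adjusted p = 0.04999). Of the 19 genes, 14 lie in a segment of 41 genes on chromosome 6, which their own shifts helped to define. With the genes of segments left out the list did not pass (5 genes, median 0.14, camera adjusted p = 0.236), a lower median being built into that choice of genes. The list did not pass without control replicate 1 (0.14, camera adjusted p = 0.0934) or without DKO replicate 2 (0.10, camera adjusted p = 0.489). Without DKO replicate 2 none of these 3 genes passed and 0 of 19 rose, and without control replicate 2 or DKO replicate 1, 2 rose. HIST1H2BC (0.70) and HIST1H2BJ (0.55) did not pass without control replicate 2, nor HIST1H2BJ without DKO replicate 1 (0.95).

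Messenger RNAs encoded by mitochondrial DNA were higher as a list at the preset correlation (camera adjusted p = 0.0130; adjusted p = 0.981 with an estimated correlation), and 0 of 13 members passed singly. Of the 13, 12 had positive values, with a median of 0.74, led by MT-ATP8 (1.21), MT-ND3 (1.51) and MT-ND2 (1.22), and adjusted over the list alone 0 rose. All 13 rose without control replicate 1 and 10 without DKO replicate 2, whereas 1 fell without control replicate 2 and 1 without DKO replicate 1. MT-ATP8, MT-ND3 and MT-ND2 passed without control replicate 1 (2.39, 3.31 and 2.99) and without DKO replicate 2 (1.68, 2.03 and 1.81). At an unadjusted edgeR p under 0.05, 3 were higher, and DESeq2 and limma-voom called 0. Mitochondrial genes took 2.53% and 0.448% of gene counts in the control libraries and 3.59% and 1.16% in the DKO libraries, so the libraries of the clones overlapped. In both clones the share was lower in replicate 2, and within each replicate number it was higher in DKO. With the replicate number as a block the list's median was 1.07, though the labels state no pairing. With GC and length trends removed the list did not pass (0.63, camera adjusted p = 0.1997). Without control replicate 2 the median was -0.0069 (camera adjusted p = 0.553), and without DKO replicate 1 it was -0.16 (camera adjusted p = 0.884), against 2.39 without control replicate 1 and 1.29 without DKO replicate 2. The mitochondrial ribosomal RNAs MT-RNR1 (-1.45) and MT-RNR2 (-1.69) fell, and the nearly identical spliceosomal RNAs RNU4-1 (1.36) and RNU4-2 (1.34) rose, in the list of 9 structural RNAs that depletion leaves (median -0.04, camera adjusted p = 0.857). Without DKO replicate 2, MT-RNR1 (-1.03), MT-RNR2 (-1.15), RNU4-1 (0.53) and RNU4-2 (0.56) did not pass and 1 of the 9 fell, and without control replicate 1, 2 rose and 3 fell. DESeq2 called 0 of the 9 and limma-voom 4, and at an unadjusted edgeR p under 0.05, 2 were higher and 3 lower. RNU4-2 did not pass with GC and length trends removed either (1.01, edgeR adjusted p = 0.0721).

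Genes of hepatocyte function moved in both directions. Of 38 tested, 5 rose, 2 fell and 31 did not pass, and 7 rose and 2 fell when adjusted over the list alone. The acute-phase protein gene HP rose from 2.08 ± 0.519 to 13.6 ± 2.57 CPM (2.69, edgeR adjusted p = 0.000132). The fetuin gene AHSG rose 3.34-fold to 533 ± 43.2 CPM (log2 fold change 1.74, edgeR adjusted p = 0.000161), and APOH (1.16), TTR (0.78) and TAT (1.38) rose as well. AFP, the fetal serum protein used as a liver tumour marker, fell from 7814 ± 610.2 to 3563 ± 165 CPM (-1.13, edgeR adjusted p = 0.0159), and the antithrombin gene SERPINC1 fell by 0.94 on the log2 scale. The list did not pass (median -0.01, camera adjusted p = 0.275). Members numbered 6 risen and 3 fallen without control replicate 1, 4 and 4 without control replicate 2 (median 0.14), 3 and 1 without DKO replicate 1 (0.05), and 2 and 0 without DKO replicate 2. HP and AHSG kept their call without any 1 library. Without DKO replicate 2, APOH (1.09, edgeR adjusted p = 0.0546), AFP (-1.09, edgeR adjusted p = 0.0501), TTR (0.70), TAT (1.48) and SERPINC1 (-0.89) did not pass. TTR (0.87), TAT (1.30) and SERPINC1 (-0.99) did not pass without DKO replicate 1, nor TTR without control replicate 2 (0.66). DESeq2 did not call SERPINC1 (DESeq2 adjusted p = 0.0705).

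Metabolic genes were mixed as well. Of 26 cholesterol genes, 3 rose (SC5D 1.11, TM7SF2 0.96 and FDFT1 0.73) and 2 fell (PMVK -1.07 and HMGCS1 -0.73), with a median of -0.07 (camera adjusted p = 0.978). Without control replicate 1, 4 rose and 3 fell, without control replicate 2, 2 and 1 (median 0.08), without DKO replicate 1, 0 and 0 (0.06), and without DKO replicate 2, 1 and 1. SC5D and HMGCS1 lie in segments with neighbour medians of 0.56 and -0.41. None of SC5D, TM7SF2, FDFT1, PMVK and HMGCS1 passed without DKO replicate 1 (0.93, 1.05, 0.86, -0.82 and -0.75). TM7SF2 (0.88), FDFT1 (0.58) and HMGCS1 (-0.71) did not pass without DKO replicate 2, FDFT1 (0.61) and HMGCS1 (-0.68) without control replicate 1, or SC5D (0.70) and PMVK (-0.44) without control replicate 2. Limma-voom did not call PMVK (limma-voom adjusted p = 0.0745). Of 17 genes of bile acid and xenobiotic metabolism, AKR1C1, AKR1B10 (1.58) and the bile acid hormone FGF19 (0.91) rose and the cytochrome CYP2B6 (-1.63) fell (median 0.10, camera adjusted p = 0.195). Without control replicate 1, 3 rose and 2 fell, without control replicate 2, 2 rose and 3 fell (median -0.034), and without DKO replicate 1 or DKO replicate 2, 1 rose and 0 fell. FGF19, CYP2B6 and AKR1B10 did not pass without DKO replicate 1 (1.07, -1.72 and 1.41) or without DKO replicate 2 (0.71, -1.51 and 1.76), nor AKR1B10 without control replicate 2 (1.42). DESeq2 called neither CYP2B6 (-1.64) nor AKR1B10 (1.59), and limma-voom did not call AKR1B10 (1.52). Of 24 hypoxia and glycolysis genes, NDRG1 and PFKFB4 (-1.06) fell, both within segments whose genes were lower (median -0.04, camera adjusted p = 0.556). The counts were 1 risen and 5 fallen without control replicate 1, and 1 fell without DKO replicate 1 (median 0.16) and 1 without DKO replicate 2. PFKFB4 did not pass without DKO replicate 1 (-0.83), without DKO replicate 2 (-1.40) or with DESeq2 (-1.08).

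Signalling and inflammatory lists each held few members that passed. Of 40 immediate early genes IER3, KLF2 and CTGF rose (median 0.12, camera adjusted p = 0.180), and the list passed without control replicate 2 (0.37, camera adjusted p = 3.37e-05) and without DKO replicate 1 (0.22, camera adjusted p = 0.00126). Without control replicate 1 its test pointed down (0.02, camera adjusted p = 0.842), with 2 risen and 5 fallen, and without control replicate 2, 7 rose. Without DKO replicate 2 its median was -0.0076 (camera adjusted p = 0.963) with 0 risen, and with an estimated correlation its adjusted p = 0.981. Of 26 NF-kB genes the complement gene C3 (1.18, edgeR adjusted p = 0.00411) and CCL20 rose and the chemokine CXCL5 fell (-1.15), with a median of -0.08 (camera adjusted p = 0.979). Among the NF-kB genes 2 rose and 4 fell without control replicate 1 (median -0.15), 3 rose and 1 fell without control replicate 2 (0.12), 2 rose and 0 fell without DKO replicate 1 (-0.0085), and 1 rose and 1 fell without DKO replicate 2 (-0.22). Of 19 interferon-stimulated genes IFITM3 and IFITM2 (1.92) rose (median 0.18, camera adjusted p = 0.226). Of these, 3 rose and 2 fell without control replicate 1, with a median of -0.14, and without control replicate 2, 3 rose. Of 20 EGFR, FGFR and MAPK feedback genes IER3 and SPRY1 (0.80) rose and the phosphatase DUSP4 (-0.84) fell (median 0.26, camera adjusted p = 0.226), and the list passed without DKO replicate 1 (0.14, camera adjusted p = 0.0485) but not without control replicate 2 (0.14, camera adjusted p = 0.0615) or with an estimated correlation (adjusted p = 0.981). Of these genes 3 rose and 3 fell without control replicate 1, 4 rose and 0 fell without control replicate 2, 2 rose and 0 fell without DKO replicate 1, and 0 passed without DKO replicate 2. Of 22 p53 targets 1 rose and 1, PLK2, fell (median 0.05, camera adjusted p = 0.802), against 3 and 2 without control replicate 1, 2 and 1 without control replicate 2, 1 and 0 without DKO replicate 1, and 0 and 0 without DKO replicate 2, where the median was -0.018. CXCL5 (-1.05), SPRY1 (0.68) and DUSP4 (-0.67) did not pass without DKO replicate 1, SPRY1 (0.92) and DUSP4 (-1.04) without DKO replicate 2, or DUSP4 (-0.56) without control replicate 2. C3 and IFITM2 kept their call without any 1 library.

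Few RNA-binding and translation genes passed. Of 22 AU-rich element binding proteins PCBP2 rose (0.77, edgeR adjusted p = 0.0443; median 0.15, camera adjusted p = 0.226), but it did not pass without control replicate 2 (0.57), DKO replicate 1 (0.82) or DKO replicate 2 (0.72). Of 28 deadenylation and decay factors none passed (median 0.02, camera adjusted p = 0.940), with the decapping factor PATL1 leading at 0.70 (edgeR adjusted p = 0.0505) and passing without control replicate 1 (0.79, edgeR adjusted p = 0.0145). At an unadjusted edgeR p under 0.05, 2 decay factors were higher and 1 lower; DESeq2 called 1 and limma-voom 0, and 3 rose and 1 fell without control replicate 1. Of 18 stress granule and RNA-sensing genes none passed and 0 reached an unadjusted edgeR p under 0.05, with 0 called by DESeq2 and limma-voom (median -0.0030, camera adjusted p = 0.945; G3BP2 -0.40), and 1 rose without control replicate 1. Of 44 ribosomal protein genes RPS25 (0.74), RPS27 (1.02) and RPL27 (0.86) rose and RPSA (-1.10) fell (median 0.17, camera adjusted p = 0.165). RPS25 and RPSA lie in segments with neighbour medians of 0.48 and -0.49, and RPS25, RPS27, RPL27 and RPSA did not pass without control replicate 2 (0.63, 0.57, 0.59 and -0.70) or without DKO replicate 1 (0.75, 0.93, 1.04 and -0.95). RPS25 (0.74) and RPL27 (0.65) did not pass without DKO replicate 2. The ribosomal list passed without control replicate 2 (0.27, camera adjusted p = 0.0186) and without DKO replicate 1 (0.32, camera adjusted p = 0.000797). Its median was 0.08 without control replicate 1 (camera adjusted p = 0.728), and without DKO replicate 2 it was 0.0037 with the test pointing down (camera adjusted p = 0.963). With an estimated correlation its adjusted p = 0.981. Of its members 4 rose and 2 fell without control replicate 1, 1 rose and 1 fell without DKO replicate 2, and 0 passed without control replicate 2 or without DKO replicate 1.

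Of 30 proliferation genes none passed (median -0.0077, camera adjusted p = 0.979), with MCM4 leading at -0.61 (edgeR adjusted p = 0.0929) and passing without control replicate 1 (-0.79, edgeR adjusted p = 0.00991). At an unadjusted edgeR p under 0.05, 2 were higher and 1 lower, DESeq2 and limma-voom called 0, and 1 rose and 1 fell without control replicate 1. Of 32 trafficking genes, an unrelated comparison list, none passed (median -0.01, camera adjusted p = 0.802; ARF1 0.50); 2 were higher at an unadjusted edgeR p under 0.05, DESeq2 and limma-voom called 0, and 2 rose without control replicate 1. Of 23 epithelial and mesenchymal genes the membrane protein PROM1 fell (-0.76, edgeR adjusted p = 0.0294; median 0.02, camera adjusted p = 0.979), though not without control replicate 2 (-0.70), DKO replicate 1 (-0.76) or DKO replicate 2 (-0.76), and without control replicate 1, 1 of these rose and 3 fell. No list of markers of other cell types passed with TMM. Of 8 fibroblast markers PDGFRA fell (median -0.40, camera adjusted p = 0.226), with 1 risen and 2 fallen without control replicate 1 and 2 fallen without control replicate 2 (median -0.09). Of 4 kidney and neural markers LHX1 rose, from 0.720 ± 0.0204 to 3.42 ± 0.362 CPM (median -0.06, camera adjusted p = 0.802), and without control replicate 1, 1 rose and 1 fell. Of 5 leukocyte markers the actin-bundling LCP1 fell (-0.77), and the T-cell receptor subunit gene CD3D rose, with 2 and 1 counts in the control libraries and 29 and 61 in the DKO libraries (median 0.62, camera adjusted p = 0.195; adjusted p = 0.981 with an estimated correlation). With ERCC totals, where the median gene was -0.68, the list passed at the preset correlation (median -0.07, camera adjusted p = 0.0305). CD3D lies in a segment of chromosome 11 whose genes were higher, and the test on the 4 markers outside segments pointed down (median 0.05, camera adjusted p = 0.970). LCP1 did not pass without DKO replicate 1 or DKO replicate 2 (-0.77 in each).

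**Figure D3:**
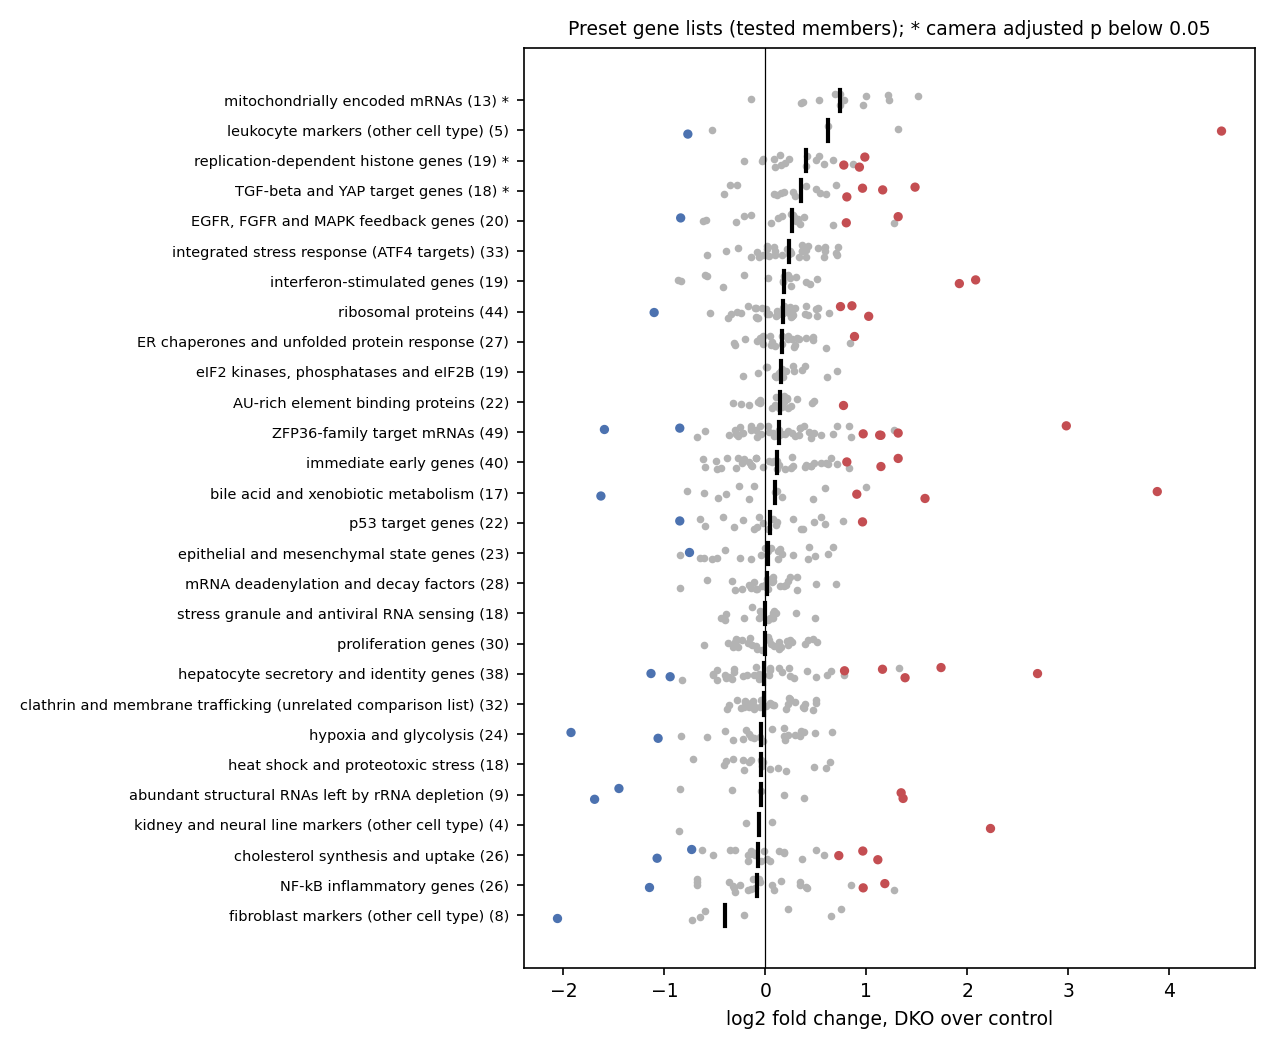
Log2 fold change of DKO over control (horizontal axis) for each tested member of the 28 lists (points; coloured where the edgeR adjusted p is under 0.05), with list medians as vertical bars and member numbers in brackets. Medians ran from -0.40 for fibroblast markers to 0.74 for mitochondrially encoded mRNAs, and 3 lists marked with an asterisk passed camera.

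In all, 3 of 28 lists passed camera at the preset correlation, and 8 did at an unadjusted p. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05, the smallest being 0.119. With fry 0 passed and 3 had an unadjusted p under 0.05. Median and mean differed in sign for 6 lists, namely the NF-kB, hepatocyte, cholesterol, epithelial and mesenchymal, kidney and neural, and trafficking genes. For proliferation genes the test pointed up while median and mean lay below 0.

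UAUUUAU is the core AU-rich element that proteins of the ZFP36 family bind. With all 4 libraries kept, transcripts with it in the 3′ UTR did not pass as a set against the rest. The 4293 genes with at least 1 copy had a median log2 fold change 0.07 above that of the 7593 without (camera adjusted p = 0.244 over 21 heptamers, unadjusted 0.175, or p = 0.686 with an estimated correlation). This difference ranked 19 among the 21 heptamers of 2 A and 5 U. With at least 2 copies, 1842 genes lay 0.10 above those without (camera adjusted p = 0.185, unadjusted 0.114, or p = 0.768 with an estimated correlation), which ranked 9 among the 21. Among genes with a 3′ UTR, the motif was present in 33.1% of 272 risen, 29.9% of 401 fallen and 36.4% of 11213 other genes, and the comparison of risen with fallen genes did not pass (Fisher's exact test, 2-sided, p = 0.397). Within quartiles of 3′ UTR length the difference was 0.07, 0.09, 0.09 and 0.06, from the shortest to the longest, and it was 0.04 with GC and length trends removed (camera adjusted p = 0.893). Matched on 3′ UTR length and AU content, the difference was 0.0043 (camera p = 0.820, n = 2839 genes with and as many without). Without matching, the difference was 0.19 without control replicate 1 and 0.16 without DKO replicate 2, but -0.043 without control replicate 2 and -0.026 without DKO replicate 1. In none of these fits did UAUUUAU stand out among the 21 heptamers.

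Neighbouring genes shifted together over parts of several chromosomes. On chromosome 11, from 78.2 to 134 Mb, 192 tested genes had a median log2 fold change of 0.52, and 30 of them rose and 2 fell. On chromosome 8, from 106 to 145 Mb, 136 genes had a median of -0.68, with 1 risen and 44 fallen. On chromosome 3, from 33.1 to 49.7 Mb, 129 genes had a median of -0.58, with 0 risen and 31 fallen. The short arm of chromosome 5, from base 196871 to 35048135, had a median of -0.59 over 62 genes, and the region from 36.6 to 65.6 Mb one of -0.41 over 73 genes. In all, 14 segments held 992 genes. They contained 174 of the 706 genes past the threshold that had a position, and 532 lay outside (252 higher and 280 lower).

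**Figure D4:**
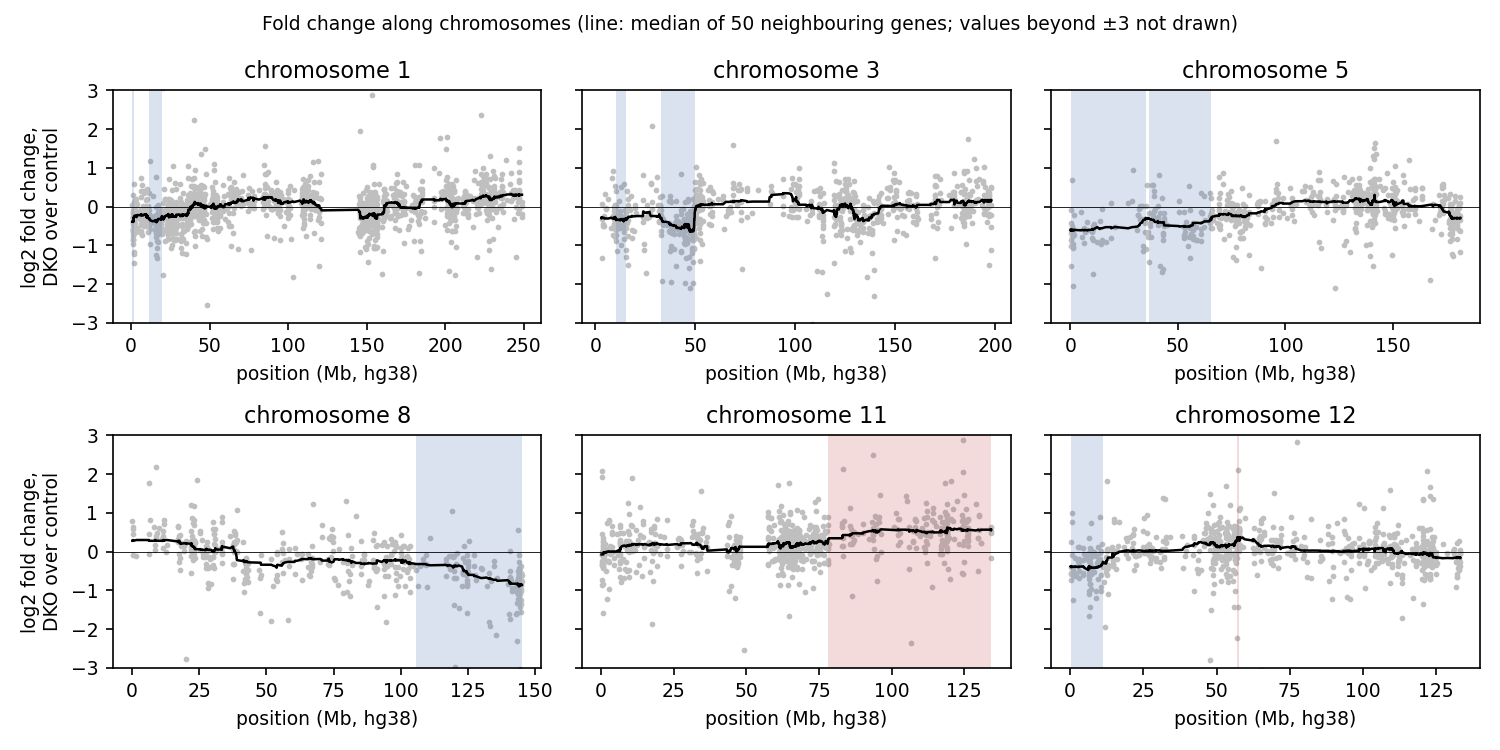
Log2 fold change of DKO over control (vertical axis) along 6 chromosomes (position in Mb, hg38); grey points are tested genes, the line is the median of 50 neighbouring genes, and shaded spans are segments with a higher (red) or lower (blue) median in DKO. The shaded end of chromosome 11 has a median of 0.52 and that of chromosome 8 one of -0.68.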

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

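The ERCC spike-ins, which the comparison of genes does not use, took a larger share of counts in both DKO libraries than in both control libraries, with a mean of 1.86% in DKO and 1.21% in control (SD 0.338 and 0.368, n = 2).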

How the results depend on the processing

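The fits with genes outside the segments and with the replicate block joined to GC and length correction, and the GC and length correction for single genes, lists and the motif, were chosen after the data were seen. The count of 718 genes became 329 with ERCC totals, 1194 without a filter, 2085 with GC and length trends removed and 152 against a 1.5-fold change, and ran from 218 to 2172 without 1 library. DESeq2 size factors, total counts, the stricter filter, DESeq2 (631), limma-voom (701) and genes outside the segments (532) left it within 1.5 times. The 458 genes changed at least 2-fold became 152 against a 1.5-fold change and ran from 218 to 899 without 1 library. Replicate numbers are shared by the groups, but the labels state no pairing. Deviations of same-numbered libraries correlated at 0.470, and with the replicate number as a block 4021 genes passed, 715 of them at least 2-fold, or 4468 with GC and length trends removed as well. Under the block ZFP36 passed at 0.49, or 0.47 with the correction, and PPP1R15A at 0.72, or 0.76. The 6 lists that passed under it were ZFP36-family targets, ATF4 targets, chaperones and unfolded protein response, TGF-beta and YAP targets, histone genes and mitochondrial mRNAs. PPP1R15A also passed at 0.73 without a filter and at 0.75 with GC and length trends removed, and ran from 0.46 to 1.02 without 1 library. With ERCC totals it was -0.05, where the median gene was -0.68. Of the 28 lists, 6 passed without a filter, 5 with ranks, 0 with an estimated correlation, 0 with fry and from 1 to 7 without 1 library, where the median of the mitochondrial mRNAs ran from -0.16 to 2.39 and their test turned downward without control replicate 2 (median -0.0069). The motif difference ran from -0.043 to 0.19 without 1 library. Of 106 other named genes, 93 kept their side of the threshold under DESeq2, 103 under limma-voom, 97 with GC and length trends removed and 63 with ERCC totals. Without 1 library, 64 to 95 did. Where no library was left out, the cause of these changes was not tested. A fit without 1 library leaves 1 library in a clone, which is assumed to vary like the other clone's. Such a fit also leaves the replicate numbers unbalanced. The motif difference was 0.19 and 0.16 without control replicate 1 or DKO replicate 2. It was -0.043 and -0.026 without control replicate 2 or DKO replicate 1. These fits do not separate the effect of 1 library from one shared by same-numbered libraries. Genes near 3 counts per library are limited by depth.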

Other observations

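The tests of segments, of their direction and of GC content on them were chosen after the segments had been seen, and the list of intestinal genes was written after the leading genes had been seen but before its own values were. The remaining tests were set down before their results were seen.

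Some genes of the intestinal epithelium fell in the DKO clone. CDX2, a transcription factor of the intestine, fell from 45.0 ± 6.12 to 12.6 ± 1.78 CPM (log2 fold change -1.84, edgeR adjusted p = 0.000238), and KLF5 fell from 79.3 ± 0.833 to 24.5 ± 2.55 CPM (-1.70). The brush-border enzyme SI (-5.21), the guanylate cyclase receptor GUCY2C (-4.51), the ferroxidase HEPH (-4.00) and the brush-border myosin MYO1A (-2.23) fell too, beside CDH17, IHH and USH1C. Of 21 tested intestinal genes not among these, 5 fell (CDHR5 -1.58, MUC13 -1.14, ISX -1.08, CLRN3 -1.04 and MEP1A -0.81), 0 rose and 16 did not pass, VIL1 (-0.16), DPP4 (0.02), APOA4 (0.89) and PRAP1 (1.28) among them. PRAP1 passed without a filter (1.29) and with GC and length trends removed (1.32), and DESeq2 did not call CDHR5 (-1.61). The median of the 21 was -0.16, but -0.35 without control replicate 1 with 22 tested, -0.25 without control replicate 2, -0.25 without DKO replicate 1, -0.24 without DKO replicate 2 and -0.49 without a filter with 30 tested. With ERCC totals, where the median gene was -0.68, it was -0.86. Without DKO replicate 1, 0 of these 21 fell (CDHR5 -1.30, MUC13 -0.98, ISX -1.27, CLRN3 -1.03 and MEP1A -0.79), and without DKO replicate 2 CDHR5 fell but not MUC13 (-1.36), ISX (-0.89), CLRN3 (-1.05) or MEP1A (-0.82). HNF4G passed without control replicate 2 (-1.04, edgeR adjusted p = 0.0111). The 9 genes named first kept their call without any 1 library.

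The hypothesis that an intestinal gene group is lower as a whole was tested on those 21 genes, whose median was -0.16 (camera p = 0.00503, or p = 0.0916 with an estimated correlation; fry p = 0.00386). After the median of 50 chromosomal neighbours was subtracted, 14 of the 14 fallen intestinal genes (100%) kept at least 50% of their fold change. This outcome was largely set by the choice of fallen genes, most of them seen before the list was written. Their neighbour medians ran from -0.28 to 0.33. These show no broad loss large enough for the falls, but a copy-number loss limited to a few genes would be missed. GC bias is argued against, since the list stayed lower with GC and length trends removed (camera p = 0.00450, n = 21 genes). The group may therefore differ between the clones, but the camera call depends on the form of the test. The form with an estimated correlation has few degrees of freedom with 4 libraries, and fry uses no preset correlation. Loss of TTP and BRF1 and a difference between clones of a line that is unrelated to the knockout remain open, because each genotype has 1 clone.

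Differences in DNA copy number between the clones may account for the chromosomal segments. Of 1449 genes in 17 segments found in the replicate 1 libraries alone, 78.3% moved in the segment's direction in the replicate 2 libraries, and 17 of the 17 medians kept their sign. The 13 segments that lay on 1 side in all 4 pairings of a DKO with a control library each kept at least 72.2% of their median with GC and length trends removed. This argues against GC bias where the libraries of a clone differed little. Control libraries differed by more, in size, than the clones on chromosome 17 (-0.40, segment median -0.34), chromosome 1 from 11.7 Mb (-0.38, -0.37) and chromosome 4 (0.36, -0.35). They differed by somewhat less than the clones on chromosome 5 from 36.6 Mb (0.31, -0.41). DKO libraries differed by somewhat less than the clones on chromosome 6 (-0.35, 0.44). In these segments GC bias is less firmly set aside, and a difference between the clones is less firmly shown. The segment of chromosome 1 from 0.825 to 1.58 Mb changed side and kept 54.0%. There GC bias and copy number cannot be told apart because the libraries of a clone differ. After their neighbours' median was subtracted, 88.0% of the genes past the threshold kept at least 50% of their fold change. Most of these genes thus moved further than their neighbours, which does not decide how far copy number accounts for the calls. Copy number of single genes is not excluded. These genes were chosen for large shifts and most lay outside segments, so few could have lost 50%. A median of 50 genes also misses changes limited to a few genes. DNA was not analysed here, and a regional change of transcription or an effect of the genotype remains open and untested.

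Libraries of the same clone differed in a way that followed GC content. The log2 difference of replicate 1 minus replicate 2 correlated with GC content across 13132 genes, which are not independent replicates, at a Spearman rho of -0.663 in control and -0.496 in DKO. GC bias in library preparation or sequencing may thus account for part of the spread between libraries, and with GC and length trends removed 2085 genes passed, 705 of them among the 718. The log2 fold changes of DKO over control also followed GC content (Spearman rho -0.254) and, less, gene length (-0.107). With the trends removed these were -0.053 and 0.0039. The comparison of the clones is thus not free of a GC trend, and what part of it is technical was not tested. What made the libraries differ remains open, since the labels name no batch. No biological explanation was tested, as both libraries of a clone have the same labels.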
